A study of Homo sapiens with 24 samples.

How the data were processed

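Total RNA from KARPAS-422 cells, extracted with Trizol and labelled with biotin, was hybridised by the submitters to 24 Affymetrix U133 Plus 2 arrays, 3 for each of 8 groups (DMSO or EZH2 inhibitor at days 1, 2, 3 and 6). The deposited values are log2 expression of 54613 probe sets, made by the authors with RMA (background correction, quantile normalization and a summary over the probes of a set) in R 2.10.1, per the submitters' processing notes. The notes do not state the log base. The values, from 1.72 to 14.33 with array medians of 4.958 to 5.032, have the range that RMA gives on the log2 scale. The number of arrays limits the precision, and RMA gives no calls of detection, so that differences of dim genes tend to be understated. No control probe sets were in the table, so the planned comparison of 3' and 5' control probe sets and of hybridisation controls is not analysed here.

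Gene names were taken from the platform's table for the 42892 probe sets that it lists with a gene. Of these, 41091 have 1 gene symbol and 1801 several, which were left out, and 11721 probe sets have no gene named here. Symbols were brought up to date by Entrez ID for 41037 probe sets, and 54 kept the old symbol. For each of 19775 genes the probe set with the highest mean over the 24 arrays was used; 9252 genes have 1 probe set and 10523 more than 1. Members of the lists that could not be matched by name to a probe set with a single symbol are not analysed here.

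Differences were tested with limma 3.58.1 (lmFit with 1 coefficient for each of the 8 groups, eBayes with default settings) in R 4.3.3, with the packages statmod 1.5.0 and data.table (1.17.8). The fit had 16 residual and 5.22 prior degrees of freedom. Contrasts were inhibitor minus DMSO at each day, their mean over the 4 days, the difference between the effects at day 6 and day 1, and DMSO day 6 minus DMSO day 1. A gene was called when its 2-sided p, adjusted by Benjamini and Hochberg over all genes of a contrast, was under 0.05. All adjusted p for single genes come from limma, since an exact test of 3 arrays against 3 cannot go below 0.1. The words rose and fell are used of genes called in that way.

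Lists of genes were tested with limma's camera, which compares a list's members with all other genes, with its preset correlation of 0.01 between genes and with p adjusted over the 27 lists of a contrast. Repeating it with the correlation estimated for each list is the alternative printed beside each call. The lists were PRC2 subunits, developmental transcription factors (classical Polycomb targets), CDK inhibitors, G1/S genes, G2/M genes, germinal centre B cell genes, B lineage genes, plasma cell genes, memory B cell and light zone exit genes, NF-kB and CD40 response genes, MHC class II genes, MHC class I genes, interferon-stimulated genes, BCL2 family and apoptosis genes, p53 target genes, unfolded protein and amino acid stress genes, cholesterol synthesis and uptake genes, MYC target and ribosome biogenesis genes, glycolysis and hypoxia genes, cytosolic heat shock genes, histone genes, chromatin modifiers other than PRC2, cell adhesion and migration genes, cytokine, TGF-beta and MAPK feedback genes, and markers of T and NK cells, of myeloid cells and of stromal, endothelial and epithelial cells. Members were written from general knowledge. Where the members called are counted, the count with p adjusted over the list alone is given if it differs. A list's mean and median are over its measured members.

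The lists, the main tests of genes and lists, the alternatives except 4, and the rule for naming genes were fixed before the data were examined. Some tests of explanations, and the comparisons within arms for the cholesterol genes, were chosen later and are named as such below. At each day the text draws on the 8 highest and 8 lowest differences among called genes whose 3 inhibitor arrays all lie above or all below the 3 DMSO arrays, leaving out symbols that say nothing to a reader (those starting with LOC, LINC, KIAA or FLJ and numbered open reading frames). It also draws on EZH2 at every day, on up to 4 called members of each list with the largest differences, on the 8 largest mean differences among genes called in 1 direction at all 4 days, and on the 6 highest and 6 lowest for the difference between day 6 and day 1 and for DMSO over time. Fewer are named where calls did not survive the loss of 1 array, and a gene named outside the rule is said to be chosen after its values were seen.

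Whether equal replicate numbers mark samples handled together was checked from the correlation of arrays of different groups after removal of group means. Its median was 0.24 for pairs with the same number and -0.13 for pairs with different numbers, and 21 of 24 arrays correlated best with their own number. The inhibitor and DMSO arrays with the same number correlated at days 1, 3 and 6 but not for number 2 at day 2. The fit without a block was therefore kept, and blocked fits are alternatives. The unblocked fit leaves differences between replicate numbers in the spread. It called 96, 869, 3221 and 8977 genes at days 1, 2, 3 and 6, against 246, 1649, 4595 and 9936 with the block over all arrays. The small counts of the early days thus depend in part on that choice. Arrays of a group correlated at 0.9935 to 0.9966, and 0 pairs of arrays had identical values.

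The alternatives were the mean of a gene's probe sets, each probe set tested on its own, leaving out the 40 percent of genes with the lowest mean (below 5.14), subtracting array medians, quantile normalization again, eBayes with trend and robust estimates, a fit to the groups compared alone, array weights, the replicate number as a block over all arrays or within each day, an adjusted p under 0.01, a log2 difference of at least 1, the estimated correlation, and leaving out each array in turn. Chosen after seeing the data were a shift of each array that sets the median gene to no change, leaving out all arrays numbered 3, and camera on the contrasts over time, with each array left out in turn for the difference between day 6 and day 1 and for DMSO over time. The filter on the mean uses all arrays, so dim genes that the inhibitor raised pass it more readily than others. The fit and camera were tested on simulated data with 19775 genes, of which 200 were changed at days 2 and 6. The fit recovered 64% and 67% of changes of 0.5 and 97% of changes of 1 at days 2 and 6. Of its calls, 13 of 174 and 10 of 174 were false. It made 0 calls at day 1, where none was simulated, and camera called 0 of 200 unchanged lists. For the difference between day 6 and day 1 the fit recovered 29% and 90%, with 6 false among 125 calls. The simulated noise was independent between genes and between arrays, and few genes were changed. The simulation thus does not test camera's preset correlation where genes of a list move together, nor an effect of the replicate number. All columns of values were used.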

Results

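Gene expression was measured in KARPAS-422, a cell line from a human diffuse large B-cell lymphoma whose label gives the EZH2 genotype as Y641N. Cells were treated with DMSO or with an inhibitor of EZH2 at 5 uM for 1, 2, 3 or 6 days, and the labels call the 3 replicates of each of the 8 groups biological. EZH2 is the catalytic subunit of Polycomb repressive complex 2, which silences genes by methylating histone H3. The 24 arrays addressed which transcripts change when a lymphoma line with mutated EZH2 is deprived of its activity, and how that response develops over 6 days. The number of arrays limits the precision. Every difference is inhibitor minus DMSO of the same day on the log2 scale, with the standard error of the fit (SE, n = 3 arrays per group), unless another comparison is named.

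The EZH2 transcript itself fell by 0.64 ± 0.12 at day 6 (adjusted p = 8.9e-05), from a group mean of 10.21 to 9.57. It was not called at days 1, 2 and 3, with differences of 0.05, -0.09 and -0.29 (adjusted p = 1, 0.76 and 0.091), although it was called at day 3 with the replicate number as a block (adjusted p = 0.0041). At day 6 the accessory subunit PHF19 fell by 1.61 ± 0.10, while PHF1 was higher by 0.87 ± 0.10 and JARID2 by 0.75 ± 0.10. JARID2 was already higher at day 2, by 0.49 ± 0.10. EZH1, the paralog of EZH2, was higher by 0.65 ± 0.12 with its brightest probe set, while 1 of its other probe sets was called lower and the mean of its probe sets was not called (adjusted p = 0.14). With 3 members higher and 5 lower of 11, the list of PRC2 subunits was not called at day 6 (mean -0.15, adjusted p = 0.62).

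At day 1 the mitochondrial carrier gene SLC25A43 rose by 1.44 ± 0.11 (adjusted p = 1.9e-07). ECI2, an isomerase of unsaturated fatty acid oxidation, rose by 1.37 ± 0.19 (adjusted p = 9e-04) and LGALSL, a galectin-like protein, by 1.06 ± 0.12 (adjusted p = 7e-05). ASB13 rose by 0.83 ± 0.11 and the integrin subunit ITGAV by 0.79 ± 0.11. ID2, an antagonist of helix-loop-helix transcription factors, was higher by 1.27 ± 0.26 (adjusted p = 0.026). That call was lost without DMSO replicate 1 or 2 (adjusted p = 0.19 and 0.056) and without inhibitor replicate 1, 2 or 3 (0.052, 0.079 and 0.15). In all, limma called 96 of 19775 genes, 94 higher and 2 lower, and 12 of the higher genes differed at least 2-fold. The count was 52 and 45 without DMSO replicates 1 and 2, 57 and 32 without inhibitor replicates 1 and 2, and 246 with the replicate number as a block or 301 with that block within each day.

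Of the 27 gene lists, 5 were called higher at day 1, each with the preset correlation alone. The interferon-stimulated genes averaged 0.28 higher (adjusted p = 0.59 with an estimated correlation), but limma called 0 of the 45 members, 4 being higher at an unadjusted p under 0.05. The average was 0.05 without inhibitor replicate 3 (adjusted p = 0.72), 0.14 without DMSO replicate 1 (adjusted p = 0.072) and 0.52 without inhibitor replicate 1. The cytokine, TGF-beta and MAPK feedback genes averaged 0.13 higher (adjusted p = 0.27 with an estimated correlation), with 1 of 38 called and 4 when adjusted over the list alone; the average was 0.09 without DMSO replicate 3 (adjusted p = 0.17). The germinal centre, MHC class II and MHC class I genes averaged 0.08 higher each (adjusted p = 0.27, 0.53 and 0.58 with an estimated correlation). Single arrays ended those calls: for MHC class II any of the 6 (adjusted p 0.057 to 0.17), for the germinal centre genes any but inhibitor replicate 2 (0.062 to 0.15), and for MHC class I DMSO replicates 1 and 3 and inhibitor replicates 2 and 3 (0.12 to 0.17).

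By day 2 IFIH1, a cytosolic sensor of double-stranded RNA, rose by 2.55 ± 0.29 (adjusted p = 8.2e-06). Other interferon-stimulated genes followed, with OASL at 2.14 ± 0.38, IFIT2 at 2.05 ± 0.27 and IFIT1 at 1.96 ± 0.40. As a list they averaged 1.02 higher, with 24 of 45 members called and 38 when adjusted over the list alone (adjusted p = 0.052 with an estimated correlation). The adhesion molecule HEPACAM2 rose by 2.34 ± 0.42, ECI2 by 2.28 ± 0.19, ID2 by 2.27 ± 0.26, SLC25A43 by 2.21 ± 0.11 and TMEM100 by 2.14 ± 0.44. Of 64 developmental transcription factors 6 were higher, among them MEIS1 by 1.89 ± 0.21, SOX9 by 1.47 ± 0.23, HOXB3 by 0.90 ± 0.13 and HOXB7 by 0.56 ± 0.10, and 1 was lower. The list was not called (mean 0.06, median -0.05, adjusted p = 0.56). The costimulatory ligand CD86 rose by 1.46 ± 0.19 and the DNA sensor AIM2 by 1.32 ± 0.24. They were 2 of 3 genes higher among 27 memory B cell and light zone exit genes (3 higher and 1 lower when adjusted over the list alone). That list was not called (mean 0.07, median -0.07, adjusted p = 0.85). NFKB1 rose by 0.54 ± 0.09, the 1 higher member of the 26 NF-kB and CD40 response genes, of which 2 were lower. That list was not called either (mean -0.14, adjusted p = 0.85).

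The lymphotoxin gene LTA fell by 1.32 ± 0.22 at day 2 (adjusted p = 0.00071), and smaller falls were found for SNX22 (-0.53 ± 0.09), ZFP36L2, which promotes mRNA decay (-0.50 ± 0.09), DUS4L (-0.49 ± 0.09) and the replication helicase component CDC45 (-0.48 ± 0.09). PECAM1 rose by 1.69 ± 0.25, ID3 by 1.05 ± 0.19, TGFBR1 by 0.84 ± 0.15 and the co-chaperone BAG3 by 0.75 ± 0.14. Of the lists, 5 were called higher and 2 lower at day 2. HLA-B rose by 0.71 ± 0.12 and HLA-C by 0.61 ± 0.08; their probe sets are of a type that may cross-hybridise within the family. The MHC class I genes averaged 0.30 higher, with 5 of 17 called and 7 when adjusted over the list alone (adjusted p = 0.052 with an estimated correlation), and the MHC class II genes 0.20 higher, with 3 of 15 called and 4 when adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). Genes of MYC targets and ribosome biogenesis averaged -0.18, with 4 of 35 lower and 8 when adjusted over the list alone, the single list of day 2 whose call held with an estimated correlation (adjusted p = 0.043). G1/S genes averaged -0.21 with 2 of 40 lower and 4 when adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Germinal centre genes averaged 0.14 (adjusted p = 0.052 with an estimated correlation, and 0.091 without DMSO replicate 3), with 5 of 34 higher and 2 lower, and 7 and 3 when adjusted over the list alone. The cytokine and feedback genes averaged 0.19 with a median of -0.01 (adjusted p = 0.15 with an estimated correlation), 6 of 38 being higher and 9 when adjusted over the list alone.

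At day 2, 869 genes were called, 706 higher and 163 lower, with at least 2-fold differences in 164 of the higher and 2 of the lower. The count was 572 and 555 without inhibitor replicates 2 and 3, and the 163 lower became 79 and 75 without DMSO replicates 2 and 3 and 100, 63 and 81 without inhibitor replicates 1, 2 and 3. The lower genes numbered 93 with the median gene set to no change and 51 with the fit limited to the groups compared. More genes were called with the replicate number as a block (1649, of which 523 lower), with that block within each day (1866 and 633) and with array weights (1441 and 482). With all arrays numbered 3 left out HOXB7, CDC45 and JARID2 were no longer called at day 2 (adjusted p = 0.091, 0.099 and 0.071).

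**Figure D1:**
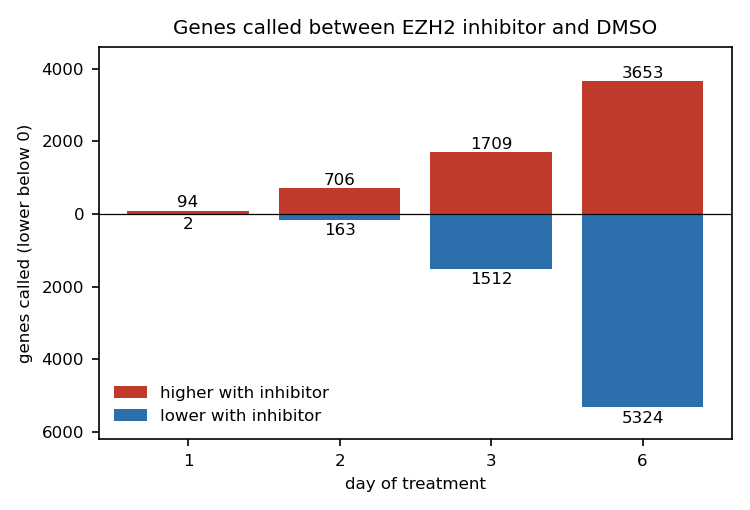
Bars give the number of genes called higher and lower with the inhibitor than with DMSO at each day (x axis, days of treatment; y axis, genes out of 19775 tested; 3 arrays per group). Genes called higher numbered 94, 706, 1709 and 3653 at days 1, 2, 3 and 6, and genes called lower 2, 163, 1512 and 5324; with the median gene set to no change the day 6 bars would be 4348 and 3444.

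Day 3 brought IFIH1 to 4.47 ± 0.29 (adjusted p = 2.9e-09). The interferon-induced genes IFI27 (3.91 ± 0.68), RSAD2 (3.45 ± 0.33) and IFIT2 (3.31 ± 0.27) also rose. At day 3, 6 lists were called higher and 5 lower. The interferon-stimulated genes averaged 1.69 higher with 41 of 45 members called, and held with an estimated correlation (adjusted p = 0.033). HEPACAM2 rose by 4.32 ± 0.42, RIN2, an exchange factor for Rab5 GTPases, by 3.42 ± 0.24, the histone gene H2AC6 by 3.35 ± 0.32, TMEM100 by 3.35 ± 0.44 and AIM2 by 3.35 ± 0.24. HLA-E rose by 1.18 ± 0.12, HLA-B by 1.01 ± 0.12 and HLA-C by 0.97 ± 0.08. The MHC class I list averaged 0.52 higher, with 12 of 17 called and 15 when adjusted over the list alone (adjusted p = 0.022 with an estimated correlation).

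At day 3 BACH2, a repressor that restrains plasma cell differentiation, rose by 1.89 ± 0.17, LPP by 1.37 ± 0.14, ASB13 by 1.25 ± 0.11, TCL1A by 1.72 ± 0.31, FCRL3 by 1.60 ± 0.24 and CD86 by 1.88 ± 0.19. JCHAIN, which joins secreted immunoglobulin, rose by 1.82 ± 0.35 and CD38 by 1.25 ± 0.21, whereas XBP1, a driver of the secretory programme, fell by 1.36 ± 0.23. The plasma cell list that holds these 3 was not called (mean 0.04, median -0.02, adjusted p = 0.93), with 5 of 31 higher and 4 lower and 5 and 6 when adjusted over the list alone. Nor was the memory B cell and light zone exit list that holds CD86 (mean 0.25, median 0.00, adjusted p = 0.19), with 3 of 27 higher and 1 lower. The germinal centre genes averaged 0.22 higher, with 10 of 34 higher and 2 lower and 11 and 3 when adjusted over the list alone (adjusted p = 0.022 with an estimated correlation). The B lineage genes averaged 0.18 higher (adjusted p = 0.2 with an estimated correlation), with 5 of 31 higher and 3 lower and 7 and 4 when adjusted over the list alone. That call was lost without DMSO replicate 1 or 3 (adjusted p = 0.1 and 0.066) or inhibitor replicate 2 or 3 (0.07 and 0.074). MHC class II genes averaged 0.23 higher with 5 of 15 called and 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation).

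LTA fell by 2.35 ± 0.22 and TNF by 1.96 ± 0.33 at day 3. The NF-kB and CD40 response genes were not called as a list (mean -0.28, adjusted p = 0.45), with 3 of 26 higher and 5 lower and 3 and 7 when adjusted over the list alone. Replication genes fell too, with CDC45 at -0.90 ± 0.09, MCM2 at -0.64 ± 0.11, CDC6 at -0.61 ± 0.10 and GINS2 at -0.58 ± 0.09. The G1/S list averaged -0.42, with 29 of 40 lower and 36 when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). The G2/M list averaged -0.15 with 10 of 55 lower and 1 higher (adjusted p = 0.39 with an estimated correlation). MYC target and ribosome biogenesis genes, among them SLC19A1 (-0.75 ± 0.12), LYAR (-0.62 ± 0.08) and MRTO4 (-0.60 ± 0.10), averaged -0.35, with 21 of 35 lower and 27 when adjusted over the list alone (adjusted p = 0.0013 with an estimated correlation). GPI fell by 0.61 ± 0.09, and the glycolysis and hypoxia genes averaged -0.14 with 9 of 30 lower and 2 higher, and 12 and 2 when adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). That list's average was -0.09 without DMSO replicate 2 (adjusted p = 0.1) and -0.08 without inhibitor replicate 1 (adjusted p = 0.14). Measured from the DMSO day 1 mean, the glycolysis and hypoxia list stood at 0.23 in DMSO and 0.09 with the inhibitor at day 3. From day 1 to day 3 the inhibitor arm changed by 0.07 and was not called by camera. The list's difference at day 3 thus includes a rise in the DMSO arm. ID2 rose by 2.53 ± 0.26, ID3 by 1.45 ± 0.19 and TGFBR1 by 1.26 ± 0.15, and the cytokine and feedback genes averaged 0.24 higher with 13 of 38 higher and 3 lower, and 14 and 3 when adjusted over the list alone (adjusted p = 0.2 with an estimated correlation).

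Genes of the amino acid response were lower than in DMSO at day 3: ASNS, which makes asparagine (-1.58 ± 0.30), ATF5 (-1.51 ± 0.30), CEBPB (-1.42 ± 0.33) and PSAT1 of serine synthesis (-1.37 ± 0.26). Those 4 calls were lost with all arrays numbered 3 left out (adjusted p = 0.055, 0.058, 0.11 and 0.064), and that of CEBPB also with the fit limited to the groups compared (adjusted p = 0.079). The list of unfolded protein and amino acid stress genes averaged -0.58, with 19 of 35 lower and 22 when adjusted over the list alone (adjusted p = 0.2 with an estimated correlation). The list's mean difference from DMSO day 1 was 0.83 and 0.59 in DMSO day 3 replicates 2 and 3 but -0.04 in DMSO replicate 1, and -0.10, -0.12 and -0.14 in the inhibitor arrays. Without DMSO replicates 1, 2 and 3 in turn the average was -0.82, -0.39 and -0.51, called each time.

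In total 3221 genes were called at day 3, 1709 higher and 1512 lower, with at least 2-fold differences in 377 and 21. Without inhibitor replicate 2 the lower genes numbered 961, with the fit limited to the groups compared 872 and with all arrays numbered 3 left out 794. With the replicate number as a block the lower genes outnumbered the higher, 2359 against 2236, as they did with that block within each day, 2496 against 2357 of 4853 genes called. With array medians subtracted the split was 1694 higher and 1560 lower, and with the median gene set to no change, which itself moves the balance, 1918 and 1110.

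**Figure D2:**
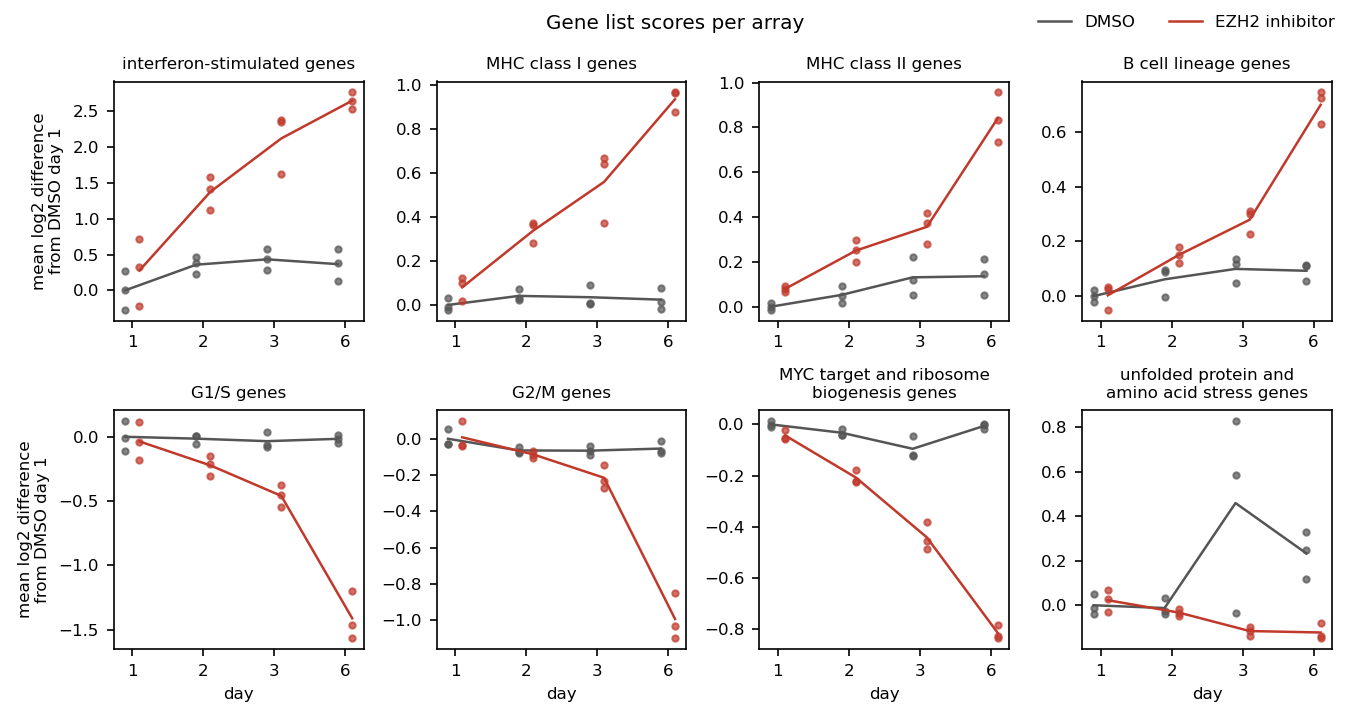
Each panel plots the mean over a list's genes of the log2 difference from the DMSO day 1 mean (y axis) against days of treatment (x axis, days spaced equally) for 8 lists, with dots for single arrays and lines through the group means of the DMSO and inhibitor arms. The arms separate by 2.28 for interferon-stimulated genes and by -1.39 for G1/S genes at day 6, and the stress genes separate at day 3, where DMSO replicates 2 and 3 lie high.

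At day 6 the interferon-induced gene IFI27 rose by 6.61 ± 0.68 (adjusted p = 4.2e-08). IFIH1 rose by 6.17 ± 0.29, RSAD2 by 4.96 ± 0.33 and IFIT2 by 4.34 ± 0.27, and 41 of the 45 interferon-stimulated genes were higher, with a mean of 2.28 (adjusted p = 0.076 with an estimated correlation). They were 1 of 9 lists called higher, and 6 were called lower. Of these 15 list calls, those of the BCL2 family and heat shock genes were lost with the mean of a gene's probe sets (adjusted p = 0.22 and 0.066) and with quantile normalization again (0.066 each), and that of the heat shock genes with the fit limited to the groups compared (0.15). The BCL2 family, heat shock, histone and adhesion calls were lost without the dimmest 40 percent of genes (0.21, 0.094, 0.58 and 0.16). MPEG1, a pore-forming protein of phagocytes and B cells, rose by 6.34 ± 0.22, HEPACAM2 by 5.78 ± 0.42, AIM2 by 5.73 ± 0.24, the zinc finger gene ZNF595 by 5.62 ± 0.18 and RIN2 by 5.50 ± 0.24. The chemokine receptor CXCR4 rose by 5.30 ± 0.35 and the death receptor TNFRSF21 by 4.63 ± 0.15. Of these genes IFIH1, MPEG1, HEPACAM2, AIM2, ZNF595, RIN2, CXCR4 and TNFRSF21 were dim in DMSO, with means of 3.08 to 4.79, where array background limits the difference that can be measured. IFI27, RSAD2 and IFIT2 had DMSO means of 6.61 to 7.01.

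The MHC class I and class II lists were both called higher at day 6, though not every member was. HLA-E was 4.3-fold higher than in DMSO (SE of the log2 difference 0.12). HLA-F was higher by 1.84 ± 0.17, HLA-G by 1.69 ± 0.17 and HLA-B by 1.61 ± 0.12. Of 17 MHC class I genes 14 were higher, 15 when adjusted over the list alone, and the chaperones CALR and PDIA3, named after their values were seen, were the 2 lower (mean 0.91, adjusted p = 0.027 with an estimated correlation). In class II, HLA-DOB rose by 1.89 ± 0.18, HLA-DOA by 1.49 ± 0.10, HLA-DRA by 0.96 ± 0.13 and HLA-DPB1 by 0.85 ± 0.11, and 12 of 15 genes were higher (mean 0.71, adjusted p = 0.024 with an estimated correlation).

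Among B lineage genes at day 6 TCL1A rose by 4.43 ± 0.31, the surface receptor genes FCRL3 by 3.26 ± 0.24 and CD72 by 2.56 ± 0.24, and CD40 by 1.80 ± 0.17. The list averaged 0.61 higher, with 18 of 31 higher and 5 lower and 19 and 6 when adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). Germinal centre genes averaged 0.36 higher, with 17 of 34 higher and 5 lower (adjusted p = 0.011 with an estimated correlation); BACH2 led with 3.86 ± 0.17, followed by LPP at 1.35 ± 0.14 and KLHL6 at 1.25 ± 0.09, while the cell cycle regulator MYBL2 fell by 1.77 ± 0.09. The germinal centre regulator BCL6, singled out after its values were seen, was not called (0.13, adjusted p = 0.084). The plasma cell list was not called (mean 0.17, adjusted p = 0.39), 10 of 31 being higher, among them JCHAIN at 3.39 ± 0.35, CD38 at 2.03 ± 0.21 and ZBP1 at 1.45 ± 0.12, and 8 lower, among them MANF at -1.15 ± 0.08 (10 and 9 when adjusted over the list alone). Nor were the memory B cell and light zone exit genes called (mean 0.48, median -0.13, adjusted p = 0.19), although AIM2, BACH2, CD86 (2.85 ± 0.19) and ZEB2 (2.12 ± 0.23) were among 8 of 27 higher, with 7 lower (8 and 8 when adjusted over the list alone).

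Replication genes fell at day 6 in all 40 measured members of the G1/S list, which averaged -1.39 (adjusted p = 0.051 with an estimated correlation). CDC45 fell by 2.21 ± 0.09, CDC6 by 2.04 ± 0.10, MCM4 by 2.02 ± 0.15 and CDCA7 by 1.95 ± 0.19. Outside the list the checkpoint kinase CHEK1 fell by 2.54 ± 0.12, ORC1 by 2.38 ± 0.13 and MCM10 by 2.33 ± 0.10. In the G2/M list 51 of 55 members were lower, 52 when adjusted over the list alone, with a mean of -0.94 (adjusted p = 0.021 with an estimated correlation); KIF2C fell by 1.59 ± 0.10, AURKB by 1.57 ± 0.14, CDC20 by 1.57 ± 0.08 and TTK by 1.51 ± 0.11. The 1 higher member was GAS2L3, named after its values were seen. The CDK inhibitor genes moved apart and were not called as a list (mean 0.03, test direction down, adjusted p = 0.99). CDKN1B rose by 0.75 ± 0.14 and CDKN2A fell by 0.73 ± 0.05, while CDKN1A, named after its values were seen, was not called (0.15, adjusted p = 0.46).

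Among lists of growth and metabolic genes, the MYC target and ribosome biogenesis list alone was called lower at day 6 also with an estimated correlation. In the MYC target and ribosome biogenesis list 34 of 35 were lower, with a mean of -0.81 (adjusted p = 6e-04 with an estimated correlation), led by CAD (-1.40 ± 0.09), SLC19A1 (-1.35 ± 0.12), LYAR (-1.32 ± 0.08) and WDR12 (-1.21 ± 0.07). MYC itself, named after its values were seen, fell by 0.73. GPI fell by 1.98 ± 0.09, PKM by 1.30 ± 0.09 and PFKP by 1.12 ± 0.07, and the glycolysis and hypoxia list averaged -0.49 with 21 of 30 lower and 2 higher, 22 and 3 when adjusted over the list alone (adjusted p = 0.098 with an estimated correlation). The fatty acid synthase gene FASN fell by 2.05 ± 0.13. Of the cholesterol genes FDPS fell by 1.43 ± 0.12, EBP by 1.41 ± 0.16 and ACAT2 by 1.35 ± 0.14, whereas the exporter ABCA1 rose by 2.95 ± 0.26. The cholesterol list averaged -0.47 with 12 of 21 lower (adjusted p = 0.34 with an estimated correlation). Measured from the DMSO day 1 mean, it stood at 0.60 in DMSO and 0.13 with the inhibitor at day 6. The glycolysis and hypoxia list stood at 0.22 and -0.27. Both differences thus include a rise in the DMSO arm. Cytosolic heat shock genes averaged -0.29 with 9 of 14 lower and 3 higher, and 10 and 3 when adjusted over the list alone (adjusted p = 0.26 with an estimated correlation), FKBP4 falling by 1.06 ± 0.07 and HSPE1 by 1.00 ± 0.07. The heat shock call was lost without DMSO replicate 2 or inhibitor replicate 2 (adjusted p = 0.064 and 0.051) and with the replicate number as a block (adjusted p = 0.068). The stress genes were not called as a list (mean -0.36, adjusted p = 0.079), with SHMT2 (-1.24 ± 0.14), PSAT1 (-1.21 ± 0.26) and ASNS (-1.17 ± 0.30) among 16 of 35 lower and 2 higher.

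Signalling and survival genes changed in both directions at day 6. ID2 rose by 4.32 ± 0.26, ARRDC3 by 2.57 ± 0.21, the MAPK inhibitor SPRED2 by 2.54 ± 0.12 and TGFBR1 by 2.20 ± 0.15, and the cytokine and feedback list averaged 0.57 with 16 of 38 higher and 6 lower, and 16 and 7 when adjusted over the list alone (adjusted p = 0.088 with an estimated correlation). LTA fell by 2.83 ± 0.22 and TNF by 2.40 ± 0.33, whereas the survival gene BCL2A1 rose by 1.71 ± 0.26. The NF-kB and CD40 response genes were not called (mean -0.10, test direction up, adjusted p = 0.61), with 7 of 26 higher and 7 lower, and 8 and 7 when adjusted over the list alone. The BCL2 family and apoptosis genes averaged 0.29 with 10 of 23 higher and 3 lower (adjusted p = 0.18 with an estimated correlation), PMAIP1, which encodes NOXA, rising by 2.20 ± 0.38 and BIK by 0.79 ± 0.18. That call was lost without DMSO replicate 1 or inhibitor replicate 2 (adjusted p = 0.06 and 0.075) and with the replicate number as a block (adjusted p = 0.06). TP53INP1 rose by 3.71 ± 0.13, SESN1 by 1.48 ± 0.12 and ZMAT3 by 1.21 ± 0.12, but the p53 target list was not called (mean 0.14, median -0.10, adjusted p = 0.84), with 5 of 23 higher and 10 lower and 6 and 10 when adjusted over the list alone.

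Histone and chromatin genes split as well at day 6. H2AC6 rose by 5.95 ± 0.32, H2BC5 by 3.20 ± 0.26, H4C8 by 2.71 ± 0.23 and H2BC21 by 2.62 ± 0.20, while H2AX and H2AZ1, named after their values were seen, fell by 0.57 and 0.56. The histone list averaged 1.08 with 8 of 17 higher and 6 lower (adjusted p = 0.35 with an estimated correlation, and 0.057 with the median gene set to no change). Chromatin modifiers other than PRC2 were not called (mean 0.00, median -0.02, test direction up, adjusted p = 0.54), with CBX7 at 1.35 ± 0.11 among 8 of 28 higher, and DOT1L at -1.41 ± 0.15 and NSD2 at -1.32 ± 0.10 among 7 lower (9 and 7 when adjusted over the list alone). Developmental transcription factors, the classical Polycomb targets, were not called as a list (mean -0.04, and 0.05 with the median gene set to no change, adjusted p = 0.64), with 7 of 64 higher and 16 lower and 7 and 13 when adjusted over the list alone. MEIS1 rose by 2.40 ± 0.21, HOXB3 by 2.37 ± 0.13 and SOX9 by 2.26 ± 0.23, whereas WT1 fell by 1.52 ± 0.21. Cell adhesion and migration genes averaged 0.38, with 15 of 42 higher and 11 lower and 16 and 11 when adjusted over the list alone (adjusted p = 0.088 with an estimated correlation, 0.063 without inhibitor replicate 2 and 0.059 with the median gene set to no change); ITGAV rose by 1.75 ± 0.11 and S100A10 by 1.51 ± 0.22.

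Markers of other cell types were not called as lists at day 6. T and NK cell markers averaged -0.16 (adjusted p = 0.46) with 8 of 27 lower, including CD247 (-1.25 ± 0.20) and CD3D (-0.58 ± 0.11), and 2 higher (7 and 1 when adjusted over the list alone). Myeloid markers averaged -0.02 (0.07 with the median gene set to no change, adjusted p = 0.65) with 8 of 25 lower and 2 higher, LYZ at 2.52 ± 0.26 and MS4A7 at 1.45 ± 0.14 (6 and 2 when adjusted over the list alone). Stromal, endothelial and epithelial markers averaged 0.10 with a median of -0.16 (adjusted p = 0.99), with 4 of 24 higher, led by the endothelial and leukocyte adhesion gene PECAM1 at 4.20 ± 0.25, and 6 lower.

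At day 6, 8977 genes were called, 3653 higher and 5324 lower, with at least 2-fold differences in 1013 and 481. The median of all genes was shifted by -0.11. With array medians subtracted 3777 genes were higher and 4881 lower, and with quantile normalization again 3512 and 5378. Setting the median gene to no change, which itself moves the balance, gave 4348 and 3444. The named genes and the called lists of day 6 kept their direction under that last setting, and 79.1% of the 8977 calls were kept.

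**Figure D3:**
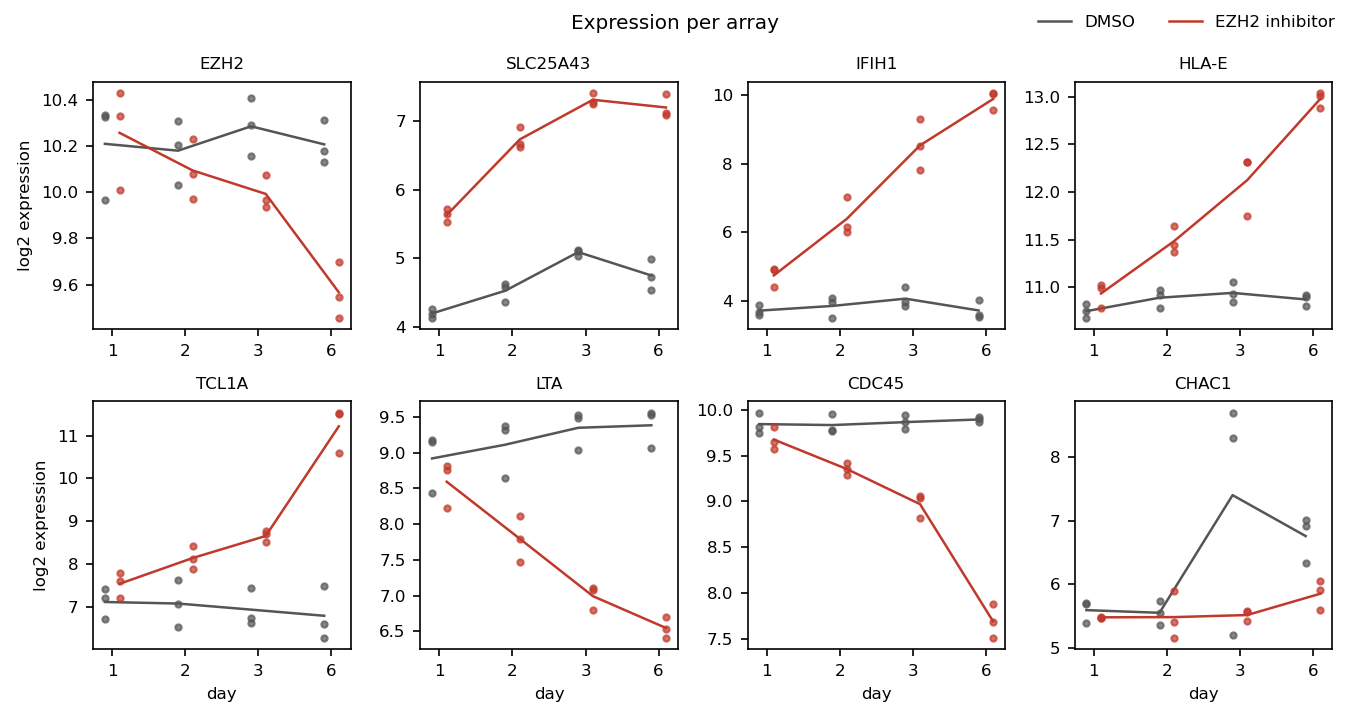
Log2 expression (y axis) of 8 genes against days of treatment (x axis, days spaced equally), with a dot for each array and lines through the group means of the DMSO and inhibitor arms. SLC25A43 differs by 1.44 from day 1, IFIH1 by 2.55, 4.47 and 6.17 at days 2, 3 and 6, and CDC45 by -0.48, -0.90 and -2.21, while the CHAC1 difference at day 3 (-1.88, and -2.98, -1.24 and -1.43 without DMSO replicates 1, 2 and 3, the last 2 not called) rests on DMSO arrays that lie high.

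Most calls recurred at the later days. Of the 94 genes higher at day 1, 91 were higher at day 2 (3.36 by chance), 88 at day 3 (8.12 by chance) and 85 at day 6 (17.4 by chance), and 5 were lower at day 6. Of the 706 genes higher at day 2, 668 were higher at day 3 (61 by chance), and of the 163 lower, 109 were lower at day 3 (12.5 by chance). Of the 1709 higher at day 3, 1594 were higher at day 6 (316 by chance), and of the 1512 lower, 1336 (407 by chance). These counts by chance take all genes as equally likely to be called. Bright genes are more readily called, and 1 estimate of a gene's spread serves all days, so sharing by chance is understated. The genes higher at day 6 had first been called at day 1 in 85 cases, at day 2 in 571, at day 3 in 958 and at day 6 in 2039. The genes lower at day 6 had first been called lower at day 2 in 126 cases, of which 105 were lower at day 3 too, at day 3 in 1231 and at day 6 in 3967.

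Higher at all 4 days were 83 genes. In these, the largest mean effects over the 4 days were those of ID2 (2.60 ± 0.13), ECI2 (2.13 ± 0.10), TNFSF8, a ligand of the TNF family (2.11 ± 0.09), SLC25A43 (2.08 ± 0.05), KLHL13 (2.02 ± 0.09), the proteoglycan core gene SRGN (1.99 ± 0.10), ARHGAP18 (1.97 ± 0.09) and AFF1 (1.93 ± 0.09). Membership of the 83 needs a call at day 1, and 33.3% to 68.8% of the day 1 calls were kept with 1 array left out. ID2 lost its day 1 call without DMSO replicate 1 or 2 or without any inhibitor replicate. For the mean effect over the 4 days limma called 8805 genes, 3379 higher and 5426 lower (4047 and 3343 with the median gene set to no change), of which 294 and 4 differed at least 2-fold.

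The effect at day 6 was compared directly with that at day 1. It differed for 5277 genes, more positive at day 6 in 2430 and more negative in 2847 (2935 and 2142 with the median gene set to no change). The difference between the effects was 6.36 ± 0.96 for IFI27, 5.75 ± 0.31 for MPEG1 and 5.66 ± 0.34 for AIM2, the last 2 dim in DMSO, and -2.51 ± 0.32 for LTA and -2.48 ± 0.17 for CHEK1. Of the lists 16 were called for this difference. Those called also with an estimated correlation were G1/S (-1.36), G2/M (-0.95), MYC targets and ribosome biogenesis (-0.77), MHC class I (0.83), MHC class II (0.63), B lineage (0.60) and germinal centre genes (0.28). Their adjusted p with an estimated correlation was 0.025, 0.017, 0.00029, 0.025, 0.025, 0.018 and 0.025. The other 9 were called with the preset correlation alone: interferon-stimulated (2.01), histone (1.07), cytokine and feedback (0.44), adhesion and migration (0.33), BCL2 family and apoptosis (0.28), heat shock (-0.36), stress (-0.38), cholesterol (-0.50) and glycolysis and hypoxia genes (-0.51). Their adjusted p with an estimated correlation was 0.071, 0.32, 0.094, 0.078, 0.12, 0.12, 0.59, 0.26 and 0.071. Of these calls those of the BCL2 family, adhesion and stress genes were lost without inhibitor day 6 replicate 2 (adjusted p = 0.051, 0.051 and 0.056), and that of the stress genes also without inhibitor day 1 replicate 2 or DMSO day 6 replicate 1 (0.051 and 0.089).

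In the DMSO arm itself day 6 was compared with day 1. INSIG1, a sterol-regulated inhibitor of cholesterol synthesis, rose by 1.45 ± 0.12 (adjusted p = 2.3e-06) and the long noncoding RNA OLMALINC by 2.08 ± 0.27 (adjusted p = 0.00041). The cholesterol synthesis and uptake genes averaged 0.60 higher, with 11 of 21 called and 17 when adjusted over the list alone (adjusted p = 0.0019 with an estimated correlation). Glycolysis and hypoxia genes averaged 0.22 higher (adjusted p = 0.021 with an estimated correlation), with limma calling 0 of 30 and 12 higher at an unadjusted p under 0.05. In the DMSO arm the germinal centre genes (0.12), B lineage genes (0.09) and NF-kB and CD40 response genes (0.29) were also called higher, with adjusted p = 0.013, 0.038 and 0.013 with an estimated correlation. The MHC class II (0.14), interferon-stimulated (0.37) and stress genes (0.23) were called with the preset correlation alone (adjusted p = 0.31, 0.43 and 0.47 with an estimated correlation). The MHC class II call was lost without DMSO day 6 replicate 2 (adjusted p = 0.069), and the interferon-stimulated genes averaged 0.23 without DMSO day 1 replicate 1. In total 57 genes were called between DMSO day 6 and DMSO day 1, 47 higher and 10 lower. The count was 25, 41 and 33 without DMSO day 1 replicates 1, 2 and 3 and 23, 36 and 30 without DMSO day 6 replicates 1, 2 and 3.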

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

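The tests chosen only after the result was seen are the 3 of the amino acid stress genes, those of array level, array distribution and dim genes for the balance at day 6, that of IFNB1, camera on the contrasts over time, and those that use the settings with the median gene set to no change or with all arrays numbered 3 left out. With 3 arrays in a group, single arrays were not tested for lying far from the others.

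The effect of the inhibitor differed between time points by a direct test of the difference, day 6 minus day 1, in 5277 genes. Among the differences far above 0 were those of IFI27 (6.36), H2AC6 (5.96), MPEG1 (5.75), AIM2 (5.66), ZNF595 (5.38) and RIN2 (5.22). The last 5 genes were dim in DMSO (means of 3.33 to 5.12 at days 1 and 6), where background limits the difference that can be measured, so the 6 cannot be ranked. Among those far below 0 were LTA (-2.51), CHEK1 (-2.48), DNAI1 (-2.47), MCM10 (-2.30), ORC1 (-2.19) and TNF (-2.13). A further 5 genes, chosen after their values were seen, were called higher at day 1 and lower at day 6: SMCO4 (-1.88, from 1.06 to -0.82), GPHN (-1.39, from 0.85 to -0.54), NOTCH2 (-1.08, from 0.68 to -0.40), EPOP (-0.88, from 0.39 to -0.48) and KHDRBS3 (-0.75, from 0.44 to -0.31). EPOP encodes a partner of PRC2 and NOTCH2 a receptor of B cell development. These 5 were chosen for opposite calls at day 1 and day 6, so a called difference between the days follows from that choice. That call held for each of the 5 whichever array was left out. The day 1 differences moved less than 1.5 times with any array left out, but several calls at single days were lost. SMCO4 was not called at day 1 without DMSO replicate 1, 2 or 3 (adjusted p = 0.077, 0.098 and 0.057) or inhibitor replicate 1 or 2 (0.13 and 0.079). EPOP was not called at day 1 without DMSO replicate 1 or 2 (0.15 and 0.12) or inhibitor replicate 1, 2 or 3 (0.082, 0.16 and 0.058), nor GPHN without DMSO replicate 2 (0.078) or inhibitor replicate 1 or 2 (0.089 and 0.064). KHDRBS3 and NOTCH2 lost their day 1 calls (0.025 and 0.05) without any 1 of the 6 arrays (0.06 to 0.13 and 0.088 to 0.31). At day 6 GPHN was not called without DMSO replicate 1 or inhibitor replicate 2 (0.061 and 0.074), nor KHDRBS3 without DMSO replicate 1 (0.063). NOTCH2 (adjusted p = 0.04 at day 6) was not called there without DMSO replicate 1, 2 or 3 (0.11, 0.055 and 0.071) or inhibitor replicate 2 or 3 (0.23 and 0.13), with differences of -0.24 and -0.62 without inhibitor replicates 2 and 1.

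When day labels were shuffled within each treatment, 7 of 100 splits, the real one included, gave at least the 5277 genes, and the highest other gave 5728. All 7 were among the 8 splits, the real one included, that kept the inhibitor arrays of each day together. Such splits leave the differences between the inhibitor days in place. The share could therefore hardly go under 0.05, and this test cannot decide on chance. The highest count among splits that moved inhibitor arrays was 5. For the mean effect over 4 days 1 of 100 shuffles within days, the real one, gave as many as 8805 genes, and the highest other gave 4330. That is the smallest share these shuffles can give, and they did not keep arrays with the same replicate number paired. Chance is thus argued against there but not excluded.

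For the single days and for DMSO over time the 6 arrays make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real counts were 96, 869, 3221 and 8977 at days 1, 2, 3 and 6 and 57 for DMSO day 6 against day 1. The highest other splits gave 0, 1, 2, 0 and 0 genes with limma, and up to 1824, 2655, 2399, 2188 and 1965 genes at an unadjusted p under 0.05. The real splits gave 1197, 3316, 5554, 10346 and 1681 by that measure, fewer than the highest other split at day 1 and for DMSO over time. At days 1, 3 and 6, where the replicate numbers pair the samples, the real split was set beside the other splits of the 4 that part all 3 pairs, whose highest counts were 0, 1 and 0. The splits that part 1 pair gave at most 0, 2 and 0. In a split that mixes the groups, a real difference between them adds to the spread of the fit. Low counts in the other splits are therefore partly built in, and their distance from the real counts does not measure chance.

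Amino acid stress genes were lower with the inhibitor at day 3, with a mean difference of -0.58 over all 35 members of the list, a call lost with an estimated correlation (adjusted p = 0.2). A fall in the inhibitor arm is argued against as the main source. Its mean change from day 1 to day 3, -0.14, matched 24.1% of the difference (16.8% to 35.5% with 1 array left out). A shift common to all arrays of day 3 cancels in a difference within that day, so its test could not decide anything. There the inhibitor arm's change was -30.2% of the DMSO arm's (-50.4% to -19.6% with 1 array left out). The DMSO arm's mean change, 0.46, matched 79.9% of the difference, consistent with a rise in DMSO cultures that the inhibitor-treated cultures did not share. Single genes show this less clearly: 4 of 35 were called higher in DMSO from day 1 to day 3 (20 higher and 4 lower when adjusted over the list alone), and 5 lower in the inhibitor arm. The DMSO change as a list was called with the preset correlation but not with an estimated one (adjusted p = 0.058). It was 0.71, 0.28 and 0.40 without DMSO day 3 replicates 1, 2 and 3. DMSO replicates 2 and 3 carried the rise, so a difference in the growth state or handling of those cultures stays open beside an effect of the inhibitor on it, and neither was tested.

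More genes were called lower than higher at day 6, 5324 against 3653, or 1.46 lower per gene higher. Differences in level or distribution left between the deposited arrays are argued against as the whole source. The ratio was 1.29 with array medians subtracted and 1.53 with quantile normalization again. The deposited values were already quantile normalized, so these settings could change little. They cannot show a shift that the first normalization made or hid. Falls of dim genes are argued against as the whole source too, since the ratio was 1.3 without the dimmest 40 percent of genes. Such falls and differences left between arrays stay open as a part of it. With genes ranked by level, 283 of the dimmest 4944 were higher and 596 lower, and 540 and 1267 of the next 4944. Of the 4943 above those, 1527 were higher and 1435 lower, and of the brightest 4944, 1303 and 2026. Lower genes thus outnumbered higher ones among the dimmer genes and among the brightest, but not between them. A shift of most genes that subtracting medians, quantile normalization again and the filter on dim genes leave in place stays open. With the median gene set to no change the ratio was 0.792, but that setting fixes the balance in advance and so decides nothing. Whether such a shift is technical or reflects a change in total RNA per cell was not tested, and these arrays hold no external standard for it.

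Interferon-stimulated genes were higher with the inhibitor from day 2, when 24 of 45 were called. With an estimated correlation the list was called at day 3 (adjusted p = 0.033) but not at days 2 and 6 (0.052 and 0.076). The arrays numbered 3 are argued against as the source, since the list's mean difference at day 2 without them was 90.7% of that with all arrays. A rise of the interferon beta transcript stays open: IFNB1 differed by 0.36 at day 2 (adjusted p = 0.54), by 0.78 at day 3 (adjusted p = 0.058) and by 1.27 at day 6 (adjusted p = 0.00065), with an SE of 0.28, but its DMSO day 1 mean of 3.87 is too dim to show a small rise. Of the 17 interferon genes measured, 1, IFNB1, was called higher at any day and 1, IFNA17, lower (-0.50 at day 6). Sensing of RNA or DNA inside the cells, another candidate source, was not tested.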

How the results depend on the processing

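Counts of called genes and lists were recomputed under each alternative, and the settings with the median gene set to no change and with all arrays numbered 3 left out were chosen after seeing the data. A count is said to move when it changed over 1.5 times; for the counts that moved, other than through a stricter threshold or fewer arrays, the cause was not tested.

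With the mean of a gene's probe sets day 1 had 53 genes rather than 96 and 3 lists rather than 5, and CDKN2B at day 6 reversed from -0.25 to 0.55. With each probe set on its own DMSO over time had 95 genes rather than 57. Quantile normalization again left 3 lists at day 1. A fit to the groups compared alone gave 46 genes and 3 lists at day 1 and 31 genes for DMSO over time. Array weights gave 160 genes and 2 lists at day 1, 1441 genes at day 2 and 92 for DMSO over time. With the replicate number as a block, 246 genes were called at day 1, 1649 at day 2 and 199 for DMSO over time, and within each day 301, 1866 and, at day 3, 4853. With the block over all arrays, EZH2 (adjusted p = 0.0041) and the histone and adhesion lists (0.023 and 0.032) became called at day 3. Within each day, EZH2 (0.0026) and the MYC targets at day 1 (0.047) became called, but not those 2 lists (0.066 each). The BCL2 family and heat shock lists at day 6 (0.06 and 0.068) and, within each day, HOXB3 at day 1 (0.055) and CD7 at day 3 (0.057) were no longer called, and the blocks changed no other call of a named gene or list.

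An adjusted p under 0.01 left 37, 464 and 1992 genes at days 1, 2 and 3 and 24 for DMSO over time. A log2 difference of at least 1 left 12, 166, 398 and 1494 genes at days 1, 2, 3 and 6, 298 for the mean effect, 1213 for the difference between day 6 and day 1, and 11 for DMSO over time. At day 6, 15 lists became 13 with the mean of a gene's probe sets or quantile normalization again and 11 without the dimmest 40 percent of genes. That filter also ended the germinal centre calls at days 1 and 2 (adjusted p = 0.11 and 0.07), the MHC class II and class I calls at day 1 (0.064 and 0.06) and the B lineage call at day 3 (0.13). Camera with an estimated correlation called 0, 1, 4 and 6 lists at days 1, 2, 3 and 6 rather than 5, 7, 11 and 15, and 4, 6, 7 and 11 at an unadjusted p under 0.05. Without all arrays numbered 3, day 1 had 3 lists, days 2 and 3 had 505 and 2044 genes, and DMSO over time had 7.

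Leaving out 1 array at a time gave 32 to 87 genes and 1 to 4 lists at day 1, 555 to 720 genes and 6 to 8 lists at day 2, 2352 to 3067 genes and 10 to 12 lists at day 3, and 7816 to 8431 genes and 12 to 16 lists at day 6. The ranges were 8264 to 8743 genes for the mean effect, 4682 to 5056 for the difference between day 6 and day 1, and 23 to 41 for DMSO over time. Lists called at day 1 numbered 1 without DMSO replicate 1.

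Of 5785 comparisons for 331 named results, 5323 kept direction and call, 457 lost the call, 4 gained it and 1 reversed. Of 1944 comparisons for 108 list results, 1826 kept both, 93 lost the call, 25 gained it and 0 reversed. A change of direction was counted only where the value was called in the main fit or in the alternative. Lists not called in the main fit had no call to lose, so the 93 losses fall on the called lists alone. Under every alternative 71 of the 108 list results and 235 of the 331 named results stayed the same. An alternative for values on a linear scale was not run, since the values are on the log2 scale. Signal over background limits what can be said of dim genes, whose differences RMA tends to shrink.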

Other observations

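The comparisons within arms for the cholesterol genes are tests chosen only after the result was seen. The 21 cholesterol genes averaged -0.47 with the inhibitor at day 6, a call lost with an estimated correlation (adjusted p = 0.34). From day 1 to day 3 they averaged 0.50 higher in the DMSO arm and 0.47 in the inhibitor arm, with 11 and 12 called higher (15 and 13 when adjusted over the list alone). With an estimated correlation that rise was called in the DMSO arm (adjusted p = 0.0033) and not in the inhibitor arm (0.07). From day 1 to day 6 they averaged 0.60 higher in the DMSO arm, where 11 were called higher (17 when adjusted over the list alone; adjusted p = 0.0019 with an estimated correlation), and 0.10 in the inhibitor arm, where 7 were called higher and 7 lower and the list was not called (adjusted p = 0.46). Within the inhibitor arm 184 genes differed from day 1 at day 2, 3219 at day 3 and 8100 at day 6, and within the DMSO arm 5, 90 and 57.

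Genes called and with no overlap between the 3 inhibitor and the 3 DMSO arrays numbered 96, 865, 3110 and 8444 at days 1, 2, 3 and 6. Among all genes the share with no overlap was 10.7%, 22.8%, 30.8% and 52.2%, where chance gives 10%. Of the genes tested, 10465 were called at no single day.

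Polycomb silences its targets, and whether genes raised by the inhibitor start from low expression was asked at day 2 with the level of each gene in the DMSO arrays of the other days. The median percentile among all genes was 57.6 for the 706 genes called higher and 72.4 for the 163 called lower. Bright genes are more readily called in either direction on arrays, so these percentiles do not decide the question, which stays open.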
